A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

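The series holds 6 one-colour arrays of biotin-labelled, amplified RNA from Saccharomyces cerevisiae, 3 of a wild type strain and 3 of the same strain overexpressing ACC1, grouped by the sample labels. Per the file headers, the deposited scanner tables give 1 median foreground intensity per spot, with 2240 spots per array and no background column. The software, and whether background was subtracted, are not given in the sources used here. The lowest spot intensity of an array lay between 733 and 1562, and a spot at 65535 was saturated, as all spots of SPO1 were.

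The authors' deposited value table holds 906 rows of a score per array, with column medians from −0.15 to −0.06. Its scale and centring are unstated. Its row numbers all occur among the scanner probe numbers, but its values did not follow the same probes (r from −0.053 to −0.035 across rows). Sorted, they followed the sorted log2 intensities above a background chosen to give the best match (R² from 0.998 to 0.999). Distributions of similar shape give a high value, so this does not show that the rows came from these intensities. Its rows were therefore given no gene names, and it served only for a count without names and for the similarity of arrays.

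Intensities were taken to log2 and quantile normalized over the yeast spots, the 26 control probes being left out, and spots of a probe were averaged. No background was subtracted, because the planned normexp correction needed background columns. Every gene had 1 probe, and all 979 systematic names were matched to the R64 gene table, used for names only. A probe counted as above background on an array when it exceeded the 95th percentile of the control probes, which 635 to 891 genes did. Of the genes named with a value, SAM1, DUR12, UGA4, CIT3, HFA1 and TRP1 did so on 2 of the 3 wild type arrays, CHO2 and ECI1 on 1 of them, and PYC2 on 1 array of each group. For a gene that did so on no array of a group, a fold is given only as a bound, against the higher of its own signal and the lowest signal among genes above the control probes on each array of that group.

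Groups were compared with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 979 genes and a threshold of 0.05. Of 36 gene lists fixed before the data were examined, 27 with at least 5 measured genes were tested with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry. The heat shock list had 0 measured genes. The rule for named genes, also fixed before the data were examined, took ACC1, up to 10 genes per direction with the largest change among those past the threshold with groups that did not overlap, the 2 leading members of each tested list, all measured fatty acid synthesis genes, and the marker and galactose genes. HHT1 and members of the TCA cycle and nitrogen lists beyond the leading 2 were named after their values were seen.

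Alternatives covered the background correction, the normalization, the averaging of spots, a filter on dim genes, the moderation of variances, array weights, the replicate number as a block, the thresholds, the value table and leaving out each array.

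The fit was tested on simulated data, 20 data sets per setting, each with 200 of 979 genes changed. In the first design, with changes of 0.3, 0.6, 1 and 2 on the log2 scale, it called too many unchanged genes: 21.8% of calls were false, and changes of 2 were estimated at 0.894 of their size. With the simulated array offsets removed exactly and no quantile normalization, 5.47% of calls were false, so the excess came from quantile normalization when many genes change strongly. A second design with changes of 0.2, 0.3, 0.5 and 0.8 was added after that result was seen. These sizes were chosen because called genes other than ACC1 changed by up to 0.86 in this same fit. After normexp with an offset of 50, ERG11, GAP1 and ADH2 exceeded them, with changes of at least 2-fold. In the second design 6.51% of calls were false, and estimates lay between 0.942 and 0.953 of the simulated size. At the 4 sizes, 17.7%, 48.5%, 93.6% and 98.9% of genes were called. Apart from array brightness, noise was drawn independently for each gene and array, so these shares need not hold for the real arrays. With no gene changed, 2 of 20 data sets gave a call. Common-median scaling gave calls in 20 of 20 such data sets, with a mean of 2.65. Removing the offsets exactly gave calls in 20 of 20, with a mean of 2.9. What gave these calls was not traced, and saturated spots were not examined as their source. These counts therefore do not show that quantile normalization is the better setting. The quantile setting was kept as planned, and common-median scaling was among the alternatives. The list test called 0 of 27 lists in 1 data set simulated with no shift and with genes independent of each other. Such data cannot show false calls that arise from correlation between the genes of a list.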

Results

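Gene expression was measured in budding yeast with 6 single-colour oligonucleotide arrays. Labelled RNA amplified from total RNA of a wild type strain was hybridized to 3 arrays, and that of the same strain overexpressing ACC1 to the other 3. ACC1 encodes acetyl-CoA carboxylase, the biotin-dependent enzyme that makes malonyl-CoA for fatty acid synthesis. Each array held 979 yeast genes, each represented by a single probe printed in 2 to 4 spots, and 26 control probes. The median yeast spot had an intensity of 4120 ± 440 on the wild type arrays and 1900 ± 114 on the ACC1 overexpression arrays (SD, n = 3 each), a 2.17-fold difference that normalization removed. The control probes were 1.86-fold brighter on the wild type arrays. The number of arrays limits the precision of every value. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

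ACC1 (YNR016C) was the most strongly changed gene. Its normalized log2 intensity was 11.77 ± 0.10 in wild type and 14.08 ± 0.07 in ACC1 overexpression (SD, n = 3 each), a log2 difference of 2.32 with a standard error of 0.07. This was a 4.99-fold higher signal, with an adjusted p of 1.18e-07 in limma. The values were read by a probe of 35 bases, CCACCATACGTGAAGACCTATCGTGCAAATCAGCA, whose longest run shared with any other probe on the array was 9 bases. Probes were compared only with each other, so this does not show whether other transcripts bind the ACC1 probe. Arrays with the same replicate number lay at the same position of the layout, and ACC1 was higher by 2.33, 2.36 and 2.26 on the log2 scale within the 3 positions. Whether background had been subtracted from the intensities is not given in the sources used here, and folds are understated where it was not. The ACC1 fold was 7.75 after a normexp correction and 8.06 when the control probes served as negative controls.

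**Figure D1:**
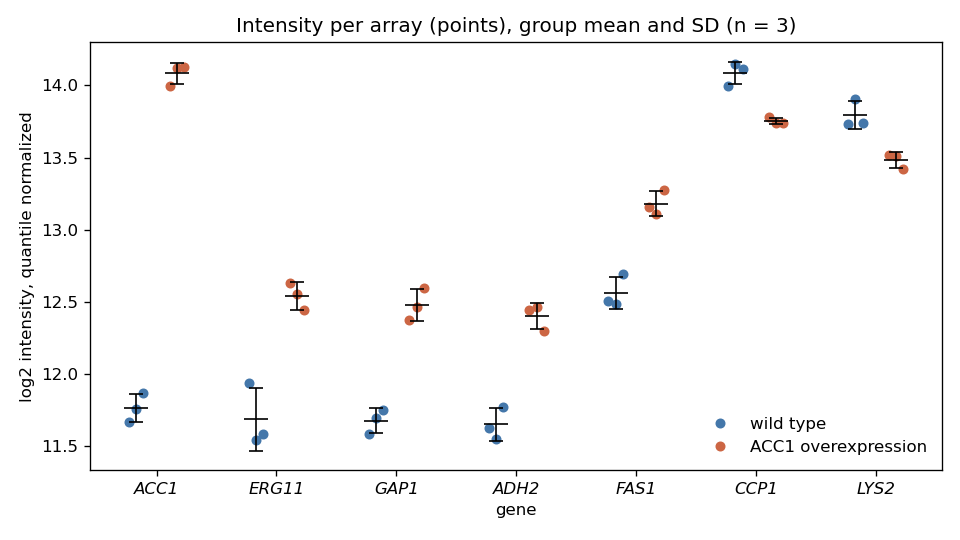
Quantile-normalized log2 intensity (vertical axis) of 7 genes (horizontal axis) on each wild type and ACC1 overexpression array. Points are single arrays, and the black bars are the group mean and SD (n = 3). ACC1 stood at 11.77 in wild type and 14.08 in ACC1 overexpression, and the 2 groups did not overlap for any of the genes shown.

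The comparison of the 2 groups asked which transcripts differed when ACC1 was overexpressed. Among genes past the threshold, the largest increases after ACC1 were those of ERG11, which encodes the lanosterol demethylase of ergosterol synthesis (log2 0.86, standard error 0.10), and GAP1, the general amino acid permease (0.80, standard error 0.07). ADH2, the glucose-repressed alcohol dehydrogenase, rose by 0.75 (standard error 0.08), and FAS1, the beta subunit of fatty acid synthase, rose by 0.62 (standard error 0.07). The next among them were HHT2, a histone H3 gene (0.58), SDH3, a subunit of succinate dehydrogenase (0.55), HOR7 (0.53), PYC1, a pyruvate carboxylase (0.49), and the cell wall protein gene HSP150 (0.45). The probes of HHT2 and of the near-identical copy HHT1 can share signal, and HHT1 stood at 0.22.

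The 8 genes that passed the threshold as lower were CCP1, the mitochondrial cytochrome c peroxidase (log2 −0.33, standard error 0.06), LYS2 of lysine synthesis (−0.31, standard error 0.07), PMP2, a proteolipid of the plasma membrane proton pump (−0.31, standard error 0.06), ELA1 (−0.30), the phospholipase C gene PLC1 (−0.28), MUM3 (−0.27), HEM1 of heme synthesis (−0.27) and HOC1 (−0.25). With the arrays scaled to a common median instead, CCP1 stood at −0.14 (adjusted p = 0.442), LYS2 at −0.22 (adjusted p = 0.124) and PMP2 at −0.21 (adjusted p = 0.267). Of the 8 decreases, ELA1 and HOC1 alone passed after normexp with an offset of 50 and with trended, robust variances, ELA1 alone passed after normexp with no offset, and 4 passed after cyclic loess. With that offset of 50, ELA1 stood at −0.59, HOC1 at −0.51, and PLC1, MUM3 and HEM1 at −0.43 each.

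Across all 979 genes, 34 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 26 higher and 8 lower in ACC1 overexpression. ACC1 was the only one with at least a 2-fold change, and the median absolute log2 change of the others was 0.33. With a common median SPO1 also passed with at least a 2-fold change. All 12 of its spots were saturated, so its signal was the same on every array before scaling. After normexp with an offset of 50, 4 genes passed with at least a 2-fold change, namely ACC1, ERG11 (1.29), GAP1 (1.21) and ADH2 (1.16), and SAM1, DUR12 and UGA4 stood at 0.80, 0.77 and 0.76. The 3 values of one group lay entirely beyond those of the other for 242 genes, or 24.7%, where chance gives 10%. With array weights 176 genes passed, 94 higher and 82 lower. Wild type replicate 2 then had a weight of 3.60, and wild type replicates 1 and 3 had 0.44 and 0.48. The ACC1 overexpression arrays had weights from 0.80 to 1.45. When the array position was a block in the model, 121 genes passed, 70 higher and 51 lower. The count fell to 5 without wild type replicate 2, to 5, 4 and 7 without ACC1 overexpression replicates 1, 2 and 3, and rose to 123 without wild type replicate 3. ACC1, GAP1, ADH2 and FAS1 passed in every one of the 18 fits, and none of the 8 decreases passed without wild type replicate 2 or without any single ACC1 overexpression array.

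**Figure D2:**
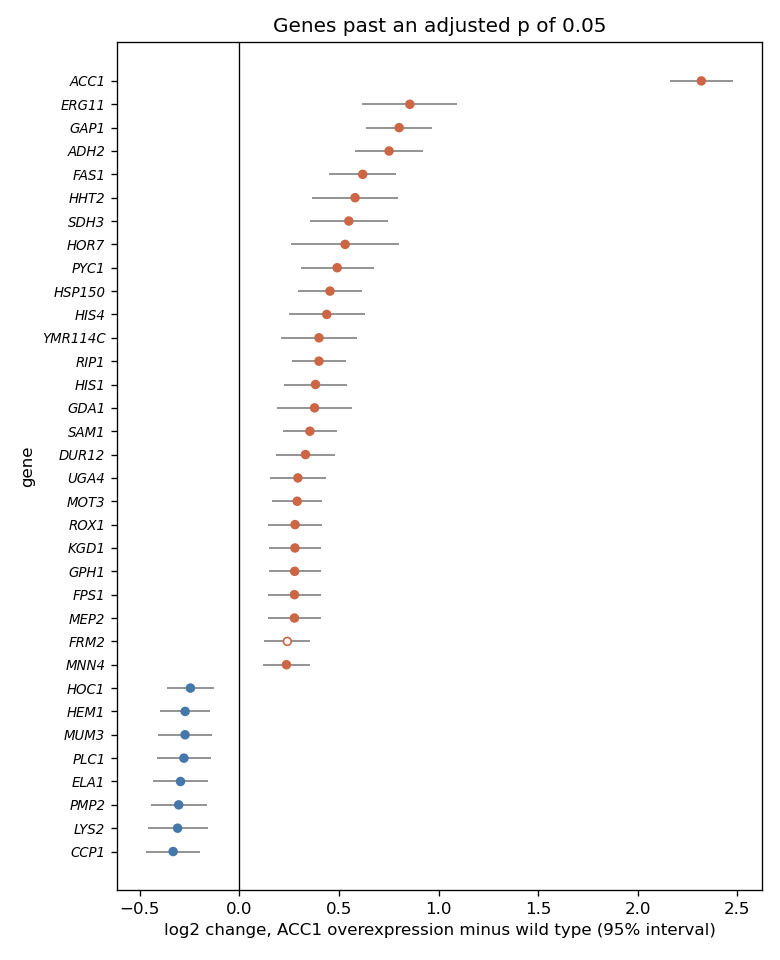
Log2 change between ACC1 overexpression and wild type (horizontal axis) of the 34 genes past an adjusted p of 0.05 (vertical axis), with 95% intervals from limma. Points to the right of 0 are the 26 genes higher in ACC1 overexpression, and those to the left are the 8 lower genes. The open point is FRM2, which was not above the control probes on any wild type array and was at least 1.005-fold higher.

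In fatty acid synthesis and elongation, 17 genes were measured and FAS1 was the only one past the threshold over all genes tested. FAS2, the alpha subunit of fatty acid synthase, stood at 0.25 (adjusted p = 0.0789), and 2 genes passed when p-values were adjusted over the list alone. The fatty acid desaturase gene OLE1 stood at −0.05 and the elongase gene ELO1 at 0.09, and the elongase genes ELO2 and ELO3 were not above the control probes on any wild type array. HFA1, the mitochondrial acetyl-CoA carboxylase, stood at 0.12. As a set, the list was not shifted against the other genes (camera adjusted p = 0.795). Among 28 genes of ergosterol synthesis, ERG11 rose and 27 did not pass, with a list median of 0.00. ERG11 missed the threshold without ACC1 overexpression replicate 2 (adjusted p = 0.0551).

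Other lipid lists held no gene past the threshold. These were phospholipid synthesis with 22 measured genes, neutral lipid storage and lipolysis with 24, sphingolipid metabolism with 20, peroxisomal beta-oxidation and peroxisome with 21, and fatty acid activation and transport with 8. The smallest p-values among them belonged to CHO2 of phosphatidylcholine synthesis, at 0.29 (adjusted p = 0.0746), and ECI1 of fatty acid oxidation, at 0.24 (adjusted p = 0.127).

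The TCA cycle was the only one of 27 lists to pass in camera with a preset correlation, higher in ACC1 overexpression (adjusted p = 0.00289). This call was lost with an estimated correlation (adjusted p = 0.829 with an estimated correlation) and with the arrays scaled to a common median (adjusted p = 0.348). In fry, which asks whether the genes of a list move one way on balance and not whether they differ from the other genes, the adjusted p was 0.134. Of 14 genes measured, SDH3 and KGD1, a subunit of alpha-ketoglutarate dehydrogenase (0.28), rose, 12 had a positive change and the list median was 0.19. KGD1 lost its call with a common median (adjusted p = 0.0671), cyclic loess (0.0827), trended, robust variances (0.0899) and normexp with an offset of 50 (0.121). CIT3 stood at 0.30 (adjusted p = 0.0561) and KGD2 at −0.20, and 4 genes passed when adjusted over the list alone. The list median was 0.27, 0.26 and 0.07 within array positions 1, 2 and 3, and its camera adjusted p was 0.00184 with the position as a block and a preset correlation.

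In nitrogen catabolite repression and amino acid uptake, 4 of 26 genes passed, all higher, and 5 higher and 1 lower passed when adjusted over the list alone. The 4 were GAP1, DUR12, the urea amidolyase (0.33), and, named after their values were seen, the permease genes UGA4 (0.29) and MEP2 (0.28), which lost its call with normexp with an offset of 50 (0.43, adjusted p = 0.0918), cyclic loess (0.0577) and trended, robust variances (0.0610). The set itself did not pass in camera (adjusted p = 0.0616), but did with a common median (0.0417), where it was the only list to pass, with cyclic loess (0.0437), with the filter on dim genes (0.0114), without wild type replicate 2 (0.0345) and without ACC1 overexpression replicate 3 (0.0313). It did not pass in camera with an estimated correlation (adjusted p = 0.829), and it passed in fry (adjusted p = 0.0466). In gluconeogenesis and the glyoxylate cycle, ADH2 rose and 8 genes did not pass, while 3 passed when adjusted over the list alone (list median 0.16, camera adjusted p = 0.0616). As a set it passed in camera with cyclic loess (0.0193), without wild type replicate 2 (0.0345) and without wild type replicate 3 (0.0277). With an estimated correlation, camera did not call this list (adjusted p = 0.829). The cell wall list passed in fry (adjusted p = 0.0466) and not in camera (adjusted p = 0.371, or 0.829 with an estimated correlation). HSP150 was the only one of its 11 genes past the threshold.

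Among 32 amino acid synthesis genes, HIS4 (0.44) and HIS1 (0.38) rose, each by 0.68 after normexp with an offset of 50, while 6 higher and 1 lower passed when adjusted over the list alone. SAM1, an S-adenosylmethionine synthetase, rose by 0.35 among 7 methionine and sulfate genes. RIP1, the Rieske subunit of the respiratory chain, rose by 0.40, or 0.72 after normexp with an offset of 50, and 8 other respiratory genes did not pass. In the general stress list, HOR7 and the glycogen phosphorylase gene GPH1 (0.28) rose among 20 genes, and 3 passed when adjusted over the list alone. Both calls were lost with a common median (adjusted p = 0.0603 for HOR7 and 0.0758 for GPH1), with trended, robust variances (0.0566 and 0.0853) and with normexp with an offset of 50 (0.0800 and 0.119). PYC1 was the only one of 14 acetyl-CoA and NADPH supply genes, HHT2 the only one of 16 histone and histone acetylation genes, and CCP1 the only one of 13 oxidative stress genes past the threshold. No gene passed over all genes tested in the lists of glycolysis (14 measured), nucleotide synthesis (16), cell cycle (15), autophagy (6), phosphate (6), drug transport (7), ribosomal proteins (5), the unfolded protein response (5) and meiosis and sporulation (9). Adjusted over the list alone, 1 higher and 1 lower passed in glycolysis, 2 higher and 1 lower in ribosomal proteins, 1 higher in meiosis and sporulation, 2 higher in acetyl-CoA and NADPH supply, 1 higher and 2 lower in oxidative stress, and 1 higher and 1 lower among methionine and sulfate genes. As sets, camera with a preset correlation called glycolysis higher with array weights (adjusted p = 0.0378) and without wild type replicate 3 (0.00359). It called ribosomal proteins higher without wild type replicate 3 (0.0139). Both lists also differed between wild type arrays, with medians of 0.29 and 0.51 in wild type replicate 3 minus replicate 1. Within array positions 1, 2 and 3, the median difference between groups was 0.23, 0.23 and −0.05 for glycolysis. For ribosomal proteins it was 0.53, 0.32 and −0.06. In the main fit with an estimated correlation, camera gave an adjusted p of 0.902 for each of these lists. PYC1 lost its call with normexp with no offset (adjusted p = 0.0604). Of 8 genes often used as strain or plasmid markers, 4 were measured. HIS3, TRP1 and ADE2 stood at −0.03, 0.04 and −0.03, while LYS2 fell. URA3, LEU2, MET15 and ADE1 were not measured, so a change in those markers could not be seen. GAL1 stood at −0.02, and GAL7 was not above the control probes on any wild type array.

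**Figure D3:**
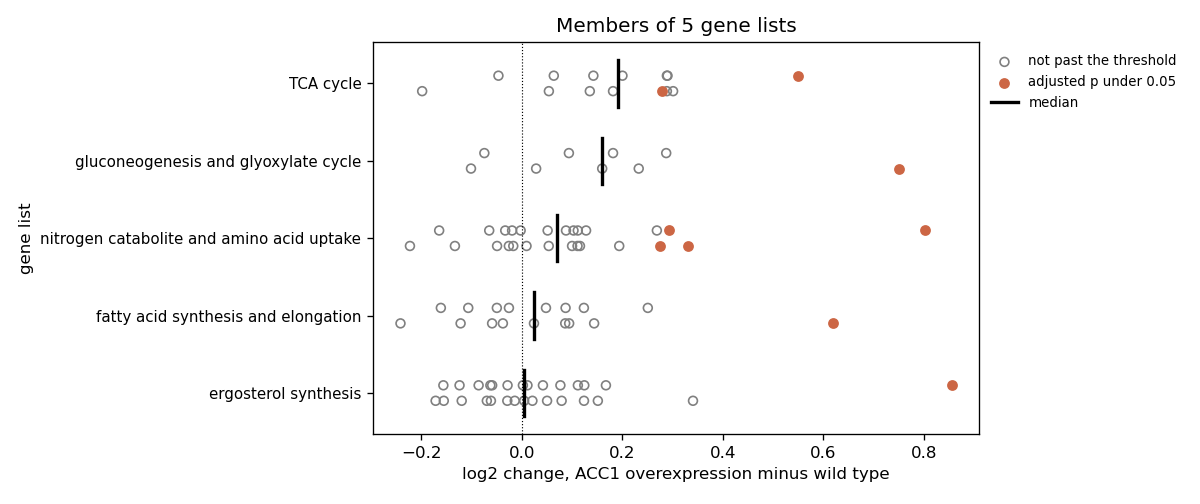
Log2 change between ACC1 overexpression and wild type (horizontal axis) of the measured genes of 5 gene lists (vertical axis). Filled points passed an adjusted p of 0.05, open points did not, and the black line is the list median, which was 0.19 for the TCA cycle and 0.00 for ergosterol synthesis.

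The design text states that profiles of the 2 groups clustered. The mean Pearson correlation across genes was 0.980 within groups and 0.964 between groups, a difference of 0.0168. An exact two-sided permutation test over the 10 splits of the arrays gave p = 0.1, the smallest value that 3 against 3 arrays allow. The correlations were not all ordered by group: wild type replicates 1 and 3 had an r of 0.960, below the 0.974 to 0.977 of wild type replicate 3 with the ACC1 overexpression arrays. Each group was hybridized on arrays of its own, and no slide or scan identity was used, so a hybridization or scan difference and the group cannot be told apart.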

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

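The alternatives with normexp on foreground alone at an offset of 50, normexp with control probes, and normexp combined with the block were chosen after the files were seen. ACC1 stayed between 2.25 and 2.36 with any array left out and reached 3.01 after background correction with control probes. The count of 34 genes moved to 74 with a common median (25 kept), 176 with array weights and 5 at an adjusted p of 0.01. It was 1 at 2-fold or more (2 with a common median, 4 or 5 after normexp). It ran from 4 to 123 with an array left out, and the cause was not tested. It was 38 with normexp at an offset of 50, of which 19 were among the 34, and 32 of 906 rows in the authors' value table. The replicate block gave 121 genes, the 34 included, and 142 after normexp. Same-numbered arrays deviated from their group means together with r of 0.467, −0.021 and 0.385. Wild type replicate 2 had r of 0.050, −0.021 and −0.029 with ACC1 overexpression replicates 1, 2 and 3. Deviations within a group cancel out, and those of wild type replicates 1 and 3 opposed each other (r = −0.833). The low r of replicate 2 therefore cannot decide whether the numbers paired the samples. The number of lists past the threshold, 1, moved to 3 with cyclic loess, 2 with the filter on dim genes, 2 with array weights and 0 with an estimated correlation, and ran from 1 to 4 with an array left out. With a common median it was 1, the nitrogen list in place of the TCA cycle. For the TCA cycle, adjusted p was 0.348 with a common median and 0.829 with an estimated correlation, and 0.000253 to 0.0247 with an array left out. The similarity difference of 0.0168 ran from 0.0116 to 0.0275 with an array left out. Of 1701 other gene and list values, 1479 kept their side of the threshold, 141 lost it, 81 gained it and 0 reversed. Most of these values belonged to genes and lists not past the threshold in the main fit, which could not lose a call. Of the 24 named genes other than ACC1 that were past it, 20 lost their call without wild type replicate 2. Without ACC1 overexpression replicates 1, 2 and 3, 20, 21 and 20 lost it, and under the other settings 0 to 11 did. Values that passed under neither setting counted as kept whatever their sign, so only a value past the threshold could count as reversed. Signal over background limits the folds of dim genes: 86 genes lay below the control probes' 95th percentile on all wild type arrays. The brightest probe per gene could not be tried, since each gene has 1 probe, nor mean against median pixels, since the files used give medians; the median over spots was used instead and gave 33 genes. A slide block was not run, since no slide identity was used.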

Other observations

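The tests of array position and of cross-hybridization were chosen only after the results were seen. Among the genes of biotin enzymes and biotin supply, a group put together after the values were seen, PYC1 and DUR12 rose with ACC1, whereas PYC2 stood at −0.03, HFA1 at 0.12 and the biotin transporter gene VHT1 at 0.12. BIO3 of biotin synthesis stood at −0.37 (limma adjusted p = 0.145). RPP1A and RPP0, which encode proteins of the ribosomal stalk, stood at 0.41 and −0.32 (limma adjusted p = 0.0784 and 0.0880).

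Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes as the real split, namely the real one with 34, and the highest of the others gave 0. With 10 splits, no share under 0.05 can be had.

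Wild type replicates 1 and 3 were less alike than wild type replicate 3 and the ACC1 overexpression arrays. Probe GC content explained 0.860% of the variance of their difference across genes, which argues against GC as its source. After normexp with cyclic loess the gap in r was −0.0121, against −0.0159 before, which argues against unequal background or a brightness trend as the whole cause. The difference between replicates 3 and 1 correlated across genes between wild type and ACC1 overexpression (r = 0.496, genes not being independent replicates), so array position, or whatever else equally numbered arrays share, may contribute. No biological explanation was tested.

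The TCA cycle list was higher in ACC1 overexpression in camera with a preset correlation, a call lost with an estimated correlation (adjusted p = 0.829 with an estimated correlation) and with a common median (adjusted p = 0.348). Its median lay at percentile 99.95 of 10000 random lists matched on intensity, which argues against the brightness of its genes. Without wild type replicate 1 the median was 71.9% of its value, which leaves open how much that array contributes. The same list had a median of 0.25 in wild type replicate 3 minus replicate 1, larger than its 0.19 between groups and at percentile 99.84 of such random lists. So high a percentile thus also arose between wild type arrays. It was not particular to the TCA cycle: glycolysis stood at percentile 99.91, ergosterol synthesis at 99.79 and ribosomal proteins at 99.58 in that difference. ACC1 overexpression itself and a hybridization difference between groups both stay open.

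PYC1 and DUR12 encode biotin-dependent enzymes, as ACC1 does, so ACC1 RNA binding to their probes was a candidate source. PYC1 stood 0.37 above HFA1, a relative of ACC1, on the log2 scale (standard error 0.12). This decides nothing, because the HFA1 probe shares no longer run with the ACC1 probe than those of PYC1 and DUR12 do, 5 bases each, and the ACC1 transcript sequence was not used here. Cross-hybridization and a response of these genes to ACC1 overexpression cannot be told apart.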
